A study of Homo sapiens with 9 samples.

How the data were processed

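RNA had been extracted with a column kit and made into stranded poly(A)-selected libraries, per the labels' protocols, from 3 groups of 3 MCF-7L tumorsphere libraries. The groups and replicate numbers were taken from the sample titles. The deposited table holds FPKM, fragments scaled by transcript length and by the number of mapped fragments, with 1 row per gene symbol and 1 column per library. It is named as read counts, but the values are not whole numbers and sum to between 511240 and 586945 per library, so they were treated as FPKM. STAR, Cufflinks and DESeq2 are named in the submitters' processing notes with the build hg19, without versions or roles, and the annotation is not given in the sources used here. No column was left unmapped.

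A count test had been planned before the data were examined. It does not suit FPKM, so limma 3.58.1 in R 4.3.3 was used in its place, on log2(FPKM + 0.5), with all 9 libraries in 1 fit, a mean for each group and a mean-variance trend in the empirical Bayes step. Genes with a mean of at least 0.5 FPKM over the 9 libraries were tested, 12174 of 20111. Fold changes are therefore on the log2(FPKM + 0.5) scale, which understates the change of low genes. P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, with a threshold of 0.05. The values after ± are SDs over the 3 libraries of a group.

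Depth was recovered from the steps between low FPKM values of genes with a single transcript, taking the effective length as the length less 200 bases. Between 67.0% and 71.1% of low values then came to a whole number of fragments within 0.05, too few to rebuild a count table. The recovered depth was 11300000, 11500000 and 9790000 fragments for vector, 11000000, 11500000 and 10800000 for wild-type PELP1 and 16300000, 21900000 and 22600000 for cytoplasmic PELP1. No 2 libraries of a group were identical or agreed within sampling noise. The median squared deviation of a pair was 0.486 to 0.677 for vector, where sampling noise gives 0.455. It was 0.616 to 0.698 for wild-type PELP1 and 0.898 to 1.498 for cytoplasmic PELP1. These values rest on rebuilt fragments, so the small excess for vector does not show more than technical spread.

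Gene lists, 33 in all, had been written down before the data were examined. Those with at least 5 measured members, 30 lists, were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were the alternatives. The estimate lay below the preset for p53 targets, ribosome biogenesis and NF-kB genes (-0.01 each) and for basal markers (-0.05). A higher p for these lists under this alternative is therefore not due to correlated members. A gene was named by a rule that was also fixed beforehand. It takes PELP1 in every library, a panel of 10 genes (ESR1, PGR, GREB1, TFF1, NCOA3, PFKFB3, PFKFB4, CD44, ALDH1A3 and ERBB2), the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups (FPKM in place of the CPM first planned, and without pseudogenes), and up to 4 members with the smallest adjusted p of each list that was called or had at least 3 called members. VEGFA, HLA-A, COL1A1, CD68, MT2A, KRT83, KRT85, KRT86 and the genes on chromosome 17 or at the ends of other chromosome segments fall outside the rule and were chosen after their values were seen.

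The fit was tested on simulated data for the 12174 genes, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. For cytoplasmic PELP1 against vector it recovered 77.6%, 100% and 100% of them, with 4.6% false calls. For wild-type PELP1 against vector it recovered 88.1%, 100% and 100%, with 3% false calls, and for cytoplasmic against wild-type PELP1 89.6%, 97% and 100%, with 5.9% false calls. The simulated noise was normal, independent between genes and equal in all groups, and no changes were planted in the lowest genes. The real groups differ in depth and in spread between replicates. These rates therefore describe the fit under its own model and are not error rates of the real calls.

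Gene order was taken from the RefSeq table of GRCh38.p14, which is not the submitters' build, so no coordinates are given. Of the 12174 tested symbols, 12028 matched it by symbol or synonym. GC content and transcript length came from GENCODE 29 and were found for 11477 of the symbols. The 95% intervals of medians came from 2000 bootstrap draws of genes. They measure the spread between genes, which are not independent replicates, and not that between libraries. The alternatives were another scaling of the libraries (median of ratios, equal FPKM sums, quantile normalization), other filters (none, or at least 1 FPKM in 3 libraries), pseudocounts of 0.1 and 1, a fit of only the 6 libraries compared, a replicate block, no variance trend, leaving out each library in turn, leaving out both cytoplasmic PELP1 replicate 1 and wild-type PELP1 replicate 2 (the library with the lowest mitochondrial mRNA in each of these groups), and leaving out the chromosome 17 genes.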

Results

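Messenger RNA was sequenced from 9 libraries of MCF-7L cells, a luminal breast cancer cell line, grown as tumorspheres, the floating clusters that form when cells are kept from attaching. PELP1, a nuclear receptor coregulator that is normally found mostly in the nucleus, had been knocked out with CRISPR, and the knockout cells then carried an empty vector, wild-type PELP1 or a PELP1 with a mutated nuclear localization signal, called cytoplasmic PELP1 below. Each group held 3 libraries. The labels do not state that these came from separate cultures, so p-values measure only the spread between libraries, which may be technical. The labels give 3 days of tumorsphere growth in one place and 5 days in another, and which holds is not known. The table listed 20111 genes in FPKM, of which 12174 passed the expression filter. Depth was recovered from the steps between low values and came to 10900000 ± 935000 fragments for vector, 11100000 ± 370000 for wild-type PELP1 and 20300000 ± 3480000 for cytoplasmic PELP1 (SD, n = 3). The shallowest cytoplasmic PELP1 library, at 16300000 fragments, was deeper than every library of the other groups, so depth and this group cannot be separated.

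PELP1 itself was read first as a check of the labels. Its mRNA stood at 8.67 ± 1.14 FPKM in the vector libraries (SD, n = 3), with single values of 9.48, 7.36 and 9.16. With wild-type PELP1 it reached 249 ± 27.1 FPKM, with single values of 275, 221 and 252. With cytoplasmic PELP1 it reached 255 ± 30.1 FPKM, with single values of 290, 234 and 242. Both constructs thus gave far more PELP1 mRNA than the vector libraries held, with log2 fold changes of 4.77 (SE 0.11, limma adjusted p = 1.94e-09) and 4.80 (SE 0.11, limma adjusted p = 1.74e-09). The difference between the 2 constructs was 0.03 on the log2 scale (SE 0.11, limma adjusted p = 0.871), within the spread between replicates. Reads of the introduced cDNA and of the edited gene cannot be told apart in these values. All libraries with a construct lay above the vector libraries. The vector libraries, from the knockout cells, still held PELP1 mRNA, so these values check that the constructs were present and not the knockout itself.

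**Figure D1:**
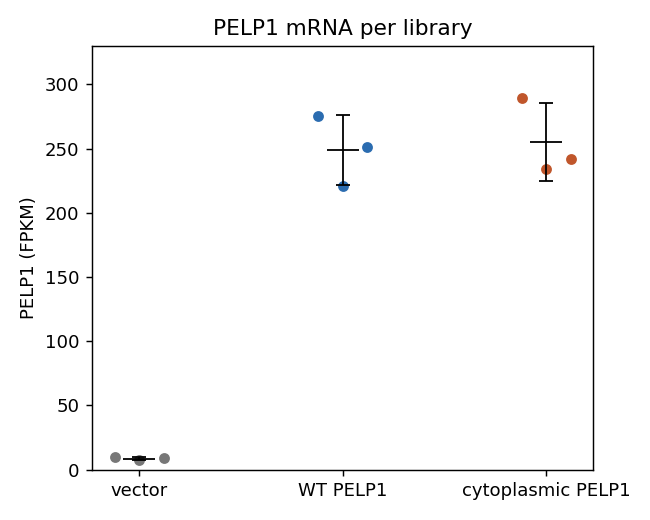
PELP1 mRNA in FPKM (vertical axis) in the 3 libraries of each group (points), with the mean and SD (black). The vector libraries lie between 7.36 and 9.48 FPKM and all 6 libraries with a PELP1 construct at 221 FPKM or above.

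The comparison of cytoplasmic PELP1 with vector asked which transcripts accompany PELP1 with a mutated nuclear localization signal. Hypoxia-inducible genes and glycolytic enzymes were higher. Of 29 measured targets of the hypoxia-inducible factors, 26 rose and 0 fell, with a median log2 fold change of 0.74 (camera adjusted p = 1.44e-16, and adjusted p = 0.0105 with an estimated correlation). BNIP3, a mitophagy receptor, rose by 1.30 on the log2 scale (SE 0.06, limma adjusted p = 4.02e-07), and the collagen-modifying enzymes PLOD2 and P4HA1 rose from 7.98 ± 0.71 to 23.6 ± 0.65 and from 20.4 ± 0.30 to 40.9 ± 1.13 FPKM (SD, n = 3). CA9, a carbonic anhydrase widely used as a hypoxia marker, was listed at 0 FPKM in all 3 vector libraries and at 3.52 ± 0.15 FPKM with cytoplasmic PELP1. VEGFA, an angiogenic factor on the same list, had a log2 fold change of 0.04 (SE 0.08, limma adjusted p = 0.738) and did not pass. Of 23 glycolysis genes, 18 rose and 0 fell (camera adjusted p = 2.39e-11, but adjusted p = 0.112 with an estimated correlation). The hypoxia and glycolysis lists share PFKFB3, PFKFB4, ALDOC and SLC2A1. Lactate dehydrogenase A, LDHA, rose from 269 ± 5.38 to 722 ± 76.2 FPKM, and the enzymes PGK1 and GPI rose by 0.79 (SE 0.05) and 0.88 (SE 0.06) on the log2 scale, with limma adjusted p-values of 2.02e-06 and 2.33e-06. The kinases PFKFB3 and PFKFB4 set the level of a sugar phosphate that activates glycolysis. Their mRNAs rose from 7.30 ± 0.14 to 18.9 ± 0.69 and from 3.17 ± 0.58 to 11 ± 1.27 FPKM. The log2 fold changes were 1.31 (SE 0.08, limma adjusted p = 1.53e-06) and 1.65 (SE 0.13, limma adjusted p = 1.18e-05).

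**Figure D2:**
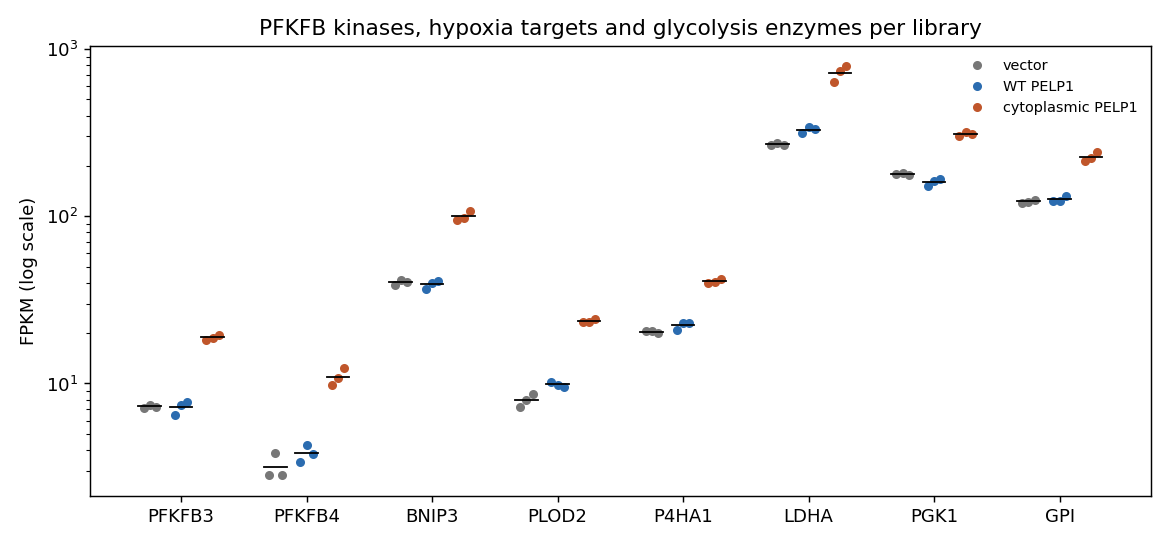
FPKM on a log scale (vertical axis) of PFKFB3, PFKFB4, 3 hypoxia targets and 3 glycolysis enzymes in the 3 libraries of each group (points, with the group mean as a black line). Every cytoplasmic PELP1 library lies above every vector and wild-type PELP1 library for these 8 genes, which were picked from the named genes for display.

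Genes of the cell cycle were also higher in the cytoplasmic PELP1 libraries. Of 47 measured, 34 rose and 1 fell, with a median log2 fold change of 0.72 (camera adjusted p = 1.44e-16, and adjusted p = 0.00139 with an estimated correlation). The topoisomerase TOP2A rose from 12.4 ± 0.52 to 33.5 ± 3.67 FPKM, the mitotic cyclin CCNB1 from 34.7 ± 1.47 to 71.0 ± 2.28 FPKM and the mitotic kinesin KIF20A from 3.92 ± 0.81 to 16.1 ± 0.61 FPKM (SD, n = 3). Of 27 p53 targets, 11 fell and 3 rose (camera adjusted p = 0.00445, but adjusted p = 0.0773 with an estimated correlation). The cell cycle inhibitor CDKN1A fell from 208 ± 1.88 to 110 ± 1.66 FPKM and the stress cytokine GDF15 from 964 ± 19.6 to 436 ± 57.8 FPKM, whereas the p53 targets BTG2 and PLK2 rose by 0.73 (SE 0.06) and 0.45 (SE 0.05) on the log2 scale, with limma adjusted p-values of 9.4e-06 and 0.000135.

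Interferon-stimulated genes rose in 28 of 39 cases and fell in 0 (camera adjusted p = 6.78e-12, and adjusted p = 0.0105 with an estimated correlation). IFIT3, an antiviral effector, rose from 46.1 ± 2.19 to 87.8 ± 2.20 FPKM, and the RNA sensor DDX58 from 23.9 ± 0.33 to 40.6 ± 0.50 FPKM. Of 18 antigen presentation genes, 9 rose and 0 fell (camera adjusted p = 0.000673, but adjusted p = 0.336 with an estimated correlation). These included the class II genes CD74, from 6.26 ± 0.58 to 23.0 ± 2.88 FPKM, and HLA-DRA, from 2.29 ± 0.73 to 6.48 ± 0.60 FPKM. The class I gene HLA-A, with a log2 fold change of -0.06 (limma adjusted p = 0.521), did not pass.

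The 13 mRNAs encoded by the mitochondrial genome all fell, with a median log2 fold change of -1.49 (camera adjusted p = 3.27e-08, but adjusted p = 0.336 with an estimated correlation, as their values move together). MT-ND1, a subunit of complex I, fell from 2689 ± 42.0 to 894 ± 418 FPKM (SE 0.32, limma adjusted p = 0.00274). The mean over the 13 mRNAs was 3662, 3670 and 3576 FPKM in the vector libraries and 731, 1976 and 1511 FPKM in the cytoplasmic PELP1 libraries, so the spread within the second group was wide. Of 36 nuclear genes of oxidative phosphorylation, 5 fell and 1 rose (camera adjusted p = 0.0293, but adjusted p = 0.654 with an estimated correlation). This last call was also lost without cytoplasmic PELP1 replicate 1, the library with the lowest mitochondrial mRNA (adjusted p = 0.375), without vector replicate 2 (0.0621), and with equal FPKM sums (0.0628) or quantile normalization (0.153), in a range from 6.04e-05 to 0.654 over the alternatives. SDHC of complex II fell from 127 ± 5.37 to 104 ± 9.39 FPKM.

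**Figure D3:**
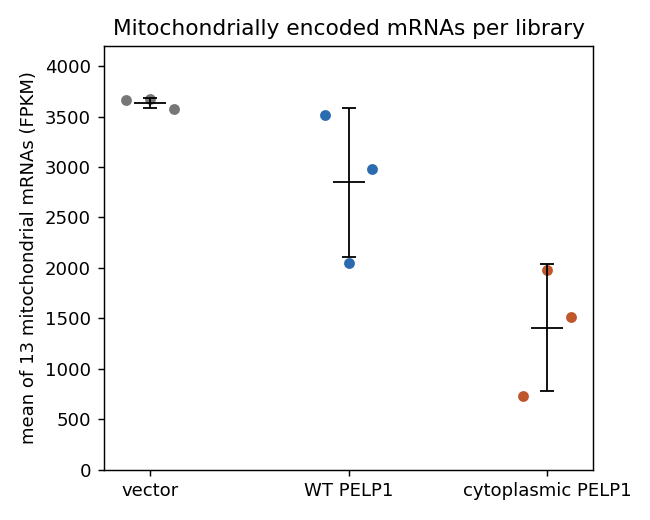
Mean FPKM over the 13 mitochondrially encoded mRNAs (vertical axis) in the 3 libraries of each group (points), with the mean and SD (black). The vector libraries lie between 3576 and 3670 FPKM, the wild-type PELP1 libraries between 2051 and 3513 FPKM and the cytoplasmic PELP1 libraries between 731 and 1976 FPKM.

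Further lists were called in the same comparison. Of 15 fatty acid synthesis genes, 7 rose and 1 fell (camera adjusted p = 0.0112, but adjusted p = 0.336 with an estimated correlation), with fatty acid synthase FASN going from 149 ± 2.79 to 230 ± 21.7 FPKM and the desaturase SCD from 494 ± 1.59 to 673 ± 24.4 FPKM. Of 18 NRF2 antioxidant genes, 8 rose and 1 fell (camera adjusted p = 0.0197, but adjusted p = 0.336 with an estimated correlation and 0.0728 without cytoplasmic PELP1 replicate 3, in a range from 0.00223 to 0.336 over the alternatives). The cystine transporter SLC7A11 rose from 1.86 ± 0.22 to 3.91 ± 1.17 FPKM. Of 36 genes of the PELP1-SENP3 complex and ribosome biogenesis, 11 rose and 1 fell (camera adjusted p = 0.0112, but adjusted p = 0.0904 with an estimated correlation), among them the RNA polymerase I subunit POLR1B with a log2 fold change of 0.43 (SE 0.07, limma adjusted p = 0.00139). Of 14 YAP/TEAD targets, 5 rose and 0 fell (camera adjusted p = 0.0418, but adjusted p = 0.336 with an estimated correlation). This call was lost without vector replicate 1 (adjusted p = 0.0983), wild-type PELP1 replicate 2 (0.0509) or cytoplasmic PELP1 replicate 1 (0.129), and with equal FPKM sums (0.0628), quantile normalization (0.0573) or the stricter filter (0.0549), in a range from 0.00119 to 0.336 over the alternatives. Of 29 epithelial and luminal identity genes, 8 fell and 2 rose (camera adjusted p = 0.00638, but adjusted p = 0.336 with an estimated correlation and 0.148 with quantile normalization, in a range from 0.00129 to 0.336 over the alternatives). The secretory protein AGR2 fell from 26.0 ± 0.45 to 12.9 ± 0.46 FPKM and the tight junction gene CLDN4 from 574 ± 12.7 to 418 ± 17 FPKM.

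Among estrogen-related genes, the 38 measured estrogen receptor targets went both ways, with 11 higher and 12 lower, and the list was not called (camera adjusted p = 0.761, with a median of -0.03 and a mean of 0.06). Its member TFF1, a classical estrogen-induced secreted peptide, fell from 4099 ± 45.5 to 1659 ± 214 FPKM, with a log2 fold change of -1.31 (SE 0.11, limma adjusted p = 1.18e-05). The progesterone receptor PGR fell from 3.58 ± 0.48 to 1.79 ± 0.07 FPKM. The secreted glycoprotein STC2 rose from 26.1 ± 1.23 to 69.1 ± 2.29 FPKM. The estrogen receptor ESR1, its target GREB1 and the coactivator NCOA3 had log2 fold changes of -0.11, -0.17 and 0.18, with limma adjusted p-values of 0.572, 0.110 and 0.0950. Without cytoplasmic PELP1 replicate 1, ESR1 and GREB1 passed with -0.31 and -0.27 (adjusted p = 0.0145 and 0.00711), in ranges from 0.0145 to 0.977 and from 0.00617 to 0.466 over the alternatives. Without cytoplasmic PELP1 replicate 3, NCOA3 passed with 0.24 (adjusted p = 0.0379, in a range from 0.0379 to 0.231). The receptor ERBB2 had a log2 fold change of -0.01 (limma adjusted p = 0.914). Of the stem cell markers, CD44 fell by 0.43 on the log2 scale (SE 0.13, limma adjusted p = 0.0331) and ALDH1A3 rose by 0.53 (SE 0.17, limma adjusted p = 0.0378). The call of CD44 was lost without vector replicate 1 or 2 (adjusted p = 0.116 and 0.0661) or cytoplasmic PELP1 replicate 1 or 3 (0.0818 and 0.0904), with equal FPKM sums (0.0654), with no filter (0.0698) and with no variance trend (0.0522), in a range from 0.0215 to 0.116. That of ALDH1A3 was lost without vector replicate 2 (0.124) or any 1 cytoplasmic PELP1 library (0.0906, 0.0863 and 0.0686), with no filter (0.0705) and with quantile normalization (0.0648), in a range from 0.0298 to 0.124.

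Among genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups, the largest fall was that of EMC10, a subunit of the endoplasmic reticulum membrane complex, which went from 18.4 ± 0.26 FPKM with vector to 0.55 ± 0.12 FPKM with cytoplasmic PELP1 (log2 fold change -4.18, SE 0.10, limma adjusted p = 1.74e-09). The desmosomal gene PKP1 fell from 17 ± 0.48 to 3.23 ± 0.07 FPKM, and MGP, an inhibitor of calcification, from 30.1 ± 3.06 to 7.50 ± 1.61 FPKM. Apart from PELP1 and the SPANX copies, the largest rises by the same rule were in HAPLN1, a hyaluronan link protein, from 0.05 ± 0.08 to 6.34 ± 1.91 FPKM, and in the bradykinin receptor BDKRB2, from 10.4 ± 0.18 to 46.2 ± 1.22 FPKM. The cancer-testis genes SPANXA1, SPANXA2 and SPANXC rose with log2 fold changes of 3.16, 3.18 and 2.93. These are near-identical copies whose reads cannot be assigned with certainty, and the values of SPANXA1 and SPANXA2 were almost equal, so they count as 1 uncertain signal.

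Over all genes, 2011 were higher and 1506 lower with cytoplasmic PELP1 than with vector (limma, Benjamini-Hochberg adjusted p under 0.05), and of these 134 and 86 changed at least 2-fold. All 3 libraries of one group lay beyond all 3 of the other for 45.6% of genes, where chance gives 10%. The split between higher and lower depended on the scaling. It was 57.2% higher in the deposited units, 70.1% with equal FPKM sums and 49.2% with median-of-ratios scaling.

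**Figure D4:**
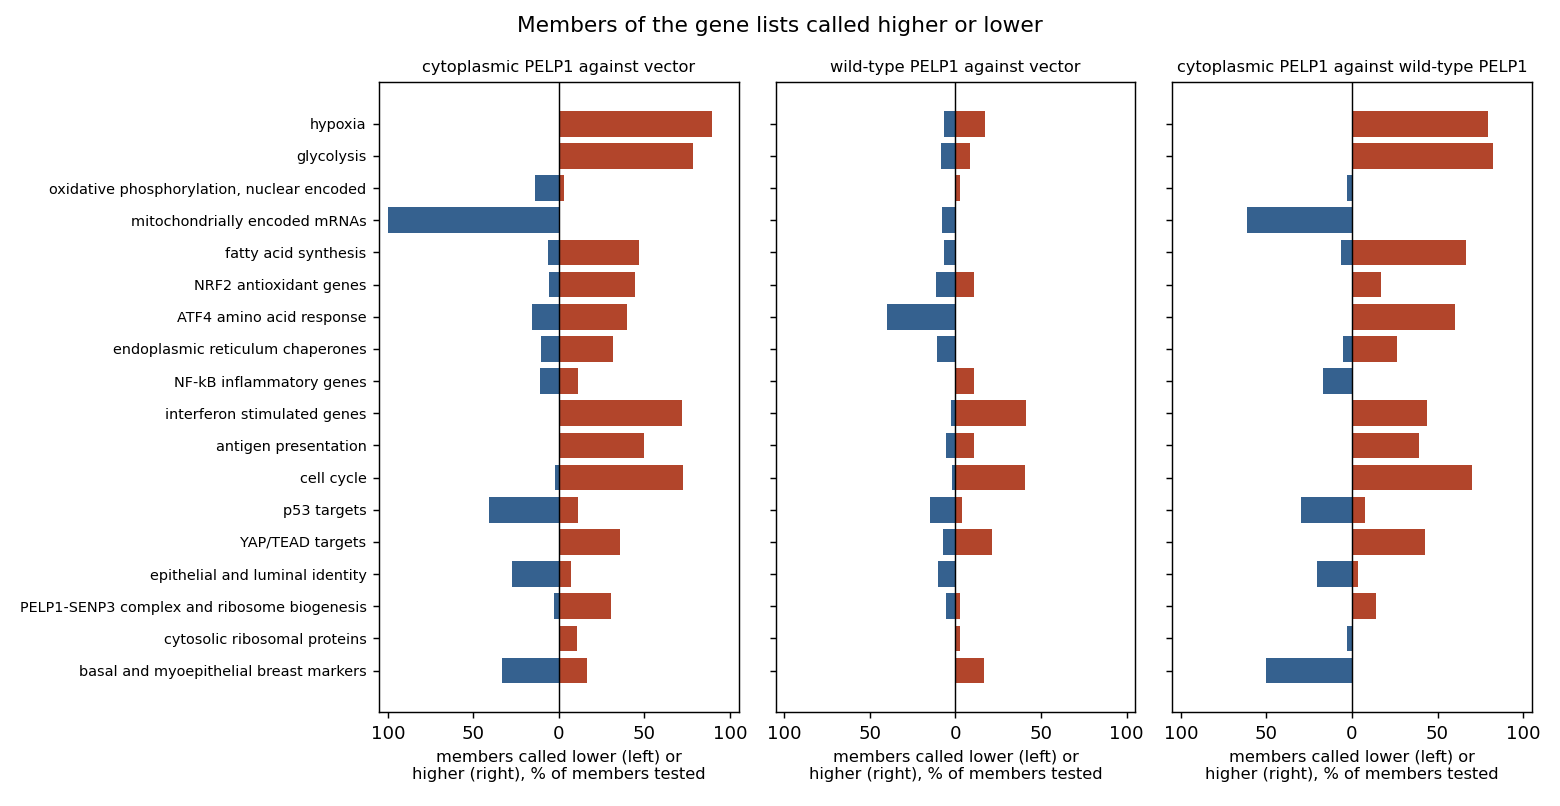
Percentage of the measured members of each gene list (rows) that were called higher (red, right) or lower (blue, left) at a limma adjusted p under 0.05 over all genes tested, for each of the 3 comparisons, and for the lists called in at least 1 comparison. Hypoxia and glycolysis bars reach far to the right in both comparisons of cytoplasmic PELP1, while wild-type PELP1 against vector has 5 of 29 hypoxia genes higher and 2 lower.

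The comparison of wild-type PELP1 with vector asked which transcripts accompany wild-type PELP1 added to the knockout cells. Cells with unedited PELP1 were not among the libraries, so whether the construct restored a normal level or exceeded it is not known. Cell cycle and interferon-stimulated genes were again higher. Of 47 cell cycle genes, 19 rose and 1 fell (camera adjusted p = 1.17e-08, and adjusted p = 0.00917 with an estimated correlation), with KIF20A going from 3.92 ± 0.81 to 8.95 ± 0.46 FPKM and CCNB1 from 34.7 ± 1.47 to 49.8 ± 2.90 FPKM (SD, n = 3). Of 39 interferon-stimulated genes, 16 rose and 1 fell (camera adjusted p = 1.17e-08, and adjusted p = 0.0343 with an estimated correlation), with DDX58 going from 23.9 ± 0.33 to 36.3 ± 1.58 FPKM. Of 25 genes of the ATF4 amino acid response, 10 fell and 0 rose (camera adjusted p = 9.39e-07, but adjusted p = 0.223 with an estimated correlation). The amino acid transporter SLC7A5 fell from 153 ± 1.99 to 95.8 ± 2.64 FPKM, the stress protein NUPR1 from 187 ± 4.58 to 114 ± 2.44 FPKM and PHGDH, the first enzyme of serine synthesis, from 41.1 ± 0.45 to 29.1 ± 2.35 FPKM. The 37 cytosolic ribosomal protein genes were called higher as a list by a median of 0.11 (camera adjusted p = 0.00917, but adjusted p = 0.837 with an estimated correlation), although only RPS6 passed singly. The list call was lost with quantile normalization (adjusted p = 0.172), in a range from 4.83e-08 to 0.837 over the alternatives. RPS6, at 0.33 on the log2 scale (SE 0.09, limma adjusted p = 0.0468), lost its call without any 1 of the vector libraries (0.143, 0.118 and 0.131) or of the wild-type PELP1 libraries (0.0939, 0.139 and 0.125), and without cytoplasmic PELP1 replicate 2 (0.0612), with no filter (0.09) and with no variance trend (0.0518), in a range from 0.000676 to 0.143.

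Hypoxia targets were not called as a list with wild-type PELP1. Of 29, 5 were higher and 2 lower, with a median of 0.02, a mean of -0.01 and an upward camera direction (adjusted p = 0.583). The glucose transporter SLC2A1 rose by 0.36 on the log2 scale (SE 0.05, limma adjusted p = 0.000930), while NDRG1, a stress-induced gene, fell by 0.85 (SE 0.15, limma adjusted p = 0.00461). Of 23 glycolysis genes, 2 rose and 2 fell, and PFKFB3 and PFKFB4 had log2 fold changes of -0.02 (SE 0.08, limma adjusted p = 0.886) and 0.24 (SE 0.13, limma adjusted p = 0.283). Of the 13 mitochondrial mRNAs, 1 fell, and the list, with a median of -0.40, was not called (camera adjusted p = 0.0702). It was called lower without wild-type PELP1 replicate 1 (adjusted p = 0.00501), without cytoplasmic PELP1 replicate 1 or 2 (0.00278 and 0.0285), with only the 6 libraries compared (0.00118) and with equal FPKM sums (0.0266), in a range from 0.00118 to 0.837 over the alternatives. TFF1, PGR, ESR1 and GREB1 had log2 fold changes of 0.13, 0.17, 0.10 and -0.11, and none passed (limma adjusted p-values of 0.475, 0.467, 0.686 and 0.418). With quantile normalization TFF1 passed, with 0.27 (adjusted p = 0.0452, in a range to 0.707 over the alternatives). CD44 fell by 0.59 (SE 0.13, limma adjusted p = 0.0178), a call lost without vector replicate 1 (0.0619) or wild-type PELP1 replicate 1 or 2 (0.0564 and 0.0668), in a range from 0.013 to 0.0743 over the alternatives. ALDH1A3 rose by 0.63 (SE 0.17, limma adjusted p = 0.038), a call lost without vector replicate 2 (0.109), wild-type PELP1 replicate 1 or 2 (0.114 and 0.110) or cytoplasmic PELP1 replicate 2 or 3 (0.0577 and 0.0506), with no filter (0.0741) and with only the 6 libraries compared (0.0646), in a range from 0.0282 to 0.116.

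By the same rule on level and overlap, the largest falls with wild-type PELP1 were in the sodium-coupled transporter SLC5A8, from 6.34 ± 0.60 to 0.57 ± 0.02 FPKM, the glutathione transferase MGST1, from 26.7 ± 6.45 to 3.91 ± 0.80 FPKM, and the membrane protein BASP1, from 19.1 ± 1.59 to 2.82 ± 0.19 FPKM. The hormone alpha chain CGA fell from 13.3 ± 1.20 to 2.87 ± 0.30 FPKM, and the immunoproteasome subunit PSMB8 from 14.7 ± 0.33 to 4.90 ± 0.37 FPKM. Apart from PELP1 and the SPANX copies, the largest rises were in the secreted protein CRISP3, from 1.80 ± 0.16 to 8.62 ± 0.87 FPKM, the neuroendocrine transcription factor ASCL1, from 1.25 ± 0.40 to 5.30 ± 0.70 FPKM, and SPTSSB, a subunit of serine palmitoyltransferase, from 63.8 ± 1.81 to 211 ± 20.4 FPKM.

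Over all genes, 649 were higher and 718 lower with wild-type PELP1 than with vector (limma), of which 46 and 49 changed at least 2-fold. Leaving out single libraries gave 391 to 822 genes higher and 419 to 917 lower. The counts fell by more than 1.5 times without any 1 of the 3 vector libraries, with 397, 414 and 417 genes higher and 455, 419 and 427 lower, without replicates 1, 2 and 3 in turn, and in 1 direction without wild-type PELP1 replicate 1 (474 lower) or replicate 2 (391 higher).

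A group of neighbouring genes was lower in this comparison, and it was chosen after its values were seen. Among the 57 tested genes between PELP1 and the end of the short arm of chromosome 17 (order from RefSeq on GRCh38.p14), 41 were called lower and 0 higher with wild-type PELP1, with a median log2 fold change of -0.43 and a 95% bootstrap interval from -0.46 to -0.33. The 57 tested genes on the centromeric side of PELP1 had a median of -0.01, with 1 lower and 1 higher. With cytoplasmic PELP1 against vector the telomeric genes had a median of 0, with 6 lower and 7 higher. Against wild-type PELP1, cytoplasmic PELP1 gave a median of 0.41, with 40 of these genes higher and 1 lower.

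**Figure D5:**
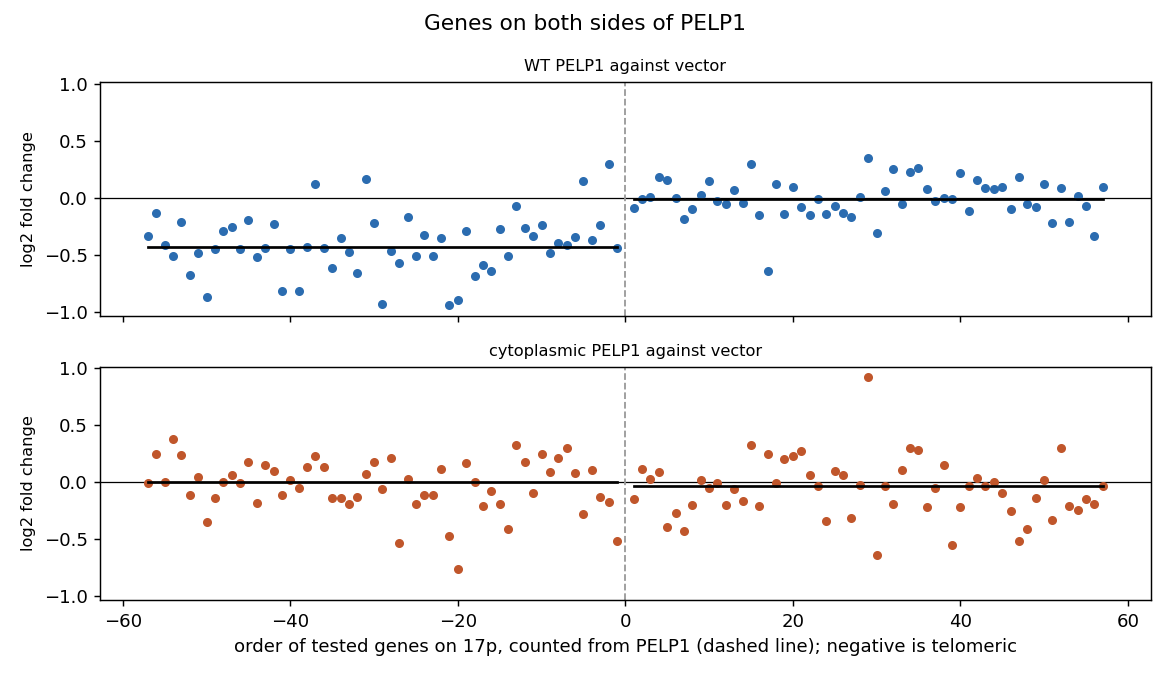
Log2 fold change against vector (vertical axes) of tested genes on the short arm of chromosome 17 in their order from PELP1 (horizontal axis, no physical scale), for wild-type PELP1 (top) and cytoplasmic PELP1 (bottom), with the median on each side as a black line. With wild-type PELP1 the telomeric median is -0.43 and the centromeric one -0.01, while with cytoplasmic PELP1 they are 0 and -0.03.

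The direct comparison of cytoplasmic with wild-type PELP1 set the 2 constructs against each other at a similar PELP1 mRNA level. The location and protein level of PELP1 were not measured here. Other differences between the lines, such as that on chromosome 17, cannot be separated from the location of PELP1. Hypoxia and glycolysis genes were higher with cytoplasmic PELP1. Of 29 hypoxia targets, 23 rose and 0 fell, with a median of 0.64 (camera adjusted p = 1.85e-20, and adjusted p = 0.00563 with an estimated correlation). Of 23 glycolysis genes, 19 rose and 0 fell (camera adjusted p = 1.05e-16, but adjusted p = 0.0553 with an estimated correlation). BNIP3 was higher by 1.34 on the log2 scale (SE 0.06, limma adjusted p = 5.15e-07). LDHA stood at 722 ± 76.2 against 330 ± 13.6 FPKM and PFKFB3 at 18.9 ± 0.69 against 7.19 ± 0.66 FPKM (SD, n = 3). PFKFB4 was higher by 1.41 on the log2 scale (SE 0.13, limma adjusted p = 7.21e-05). By the rule on level and overlap the largest rise was that of NDRG1, at 2.10 on the log2 scale (SE 0.15, limma adjusted p = 7.92e-06).

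Further lists differed between the 2 constructs. Of 47 cell cycle genes, 33 were higher and 0 lower (camera adjusted p = 4.26e-15, and adjusted p = 0.00191 with an estimated correlation). Of 39 interferon-stimulated genes, 17 were higher and 0 lower (camera adjusted p = 3.29e-06, and adjusted p = 0.0485 with an estimated correlation). Of 27 p53 targets, 8 were lower and 2 higher (camera adjusted p = 7.49e-05, and adjusted p = 0.0293 with an estimated correlation). These 4 lists, with hypoxia, were the ones whose calls held with an estimated correlation. Of 25 ATF4 response genes, 15 were higher and 0 lower (camera adjusted p = 4.3e-10, but adjusted p = 0.0583 with an estimated correlation), with SLC7A5 at 159 ± 2.36 against 95.8 ± 2.64 FPKM and PHGDH at 55.9 ± 2.92 against 29.1 ± 2.35 FPKM. Of 15 fatty acid synthesis genes, 10 were higher and 1 lower (camera adjusted p = 7.55e-05, but adjusted p = 0.105 with an estimated correlation). Antigen presentation genes were higher in 7 of 18 cases and lower in 0 (camera adjusted p = 0.000164, but adjusted p = 0.231 with an estimated correlation), led by PSMB8 at 19.4 ± 1.37 against 4.90 ± 0.37 FPKM. Of the 13 mitochondrial mRNAs, 8 were lower and 5 did not pass, with a median of -1.05 (camera adjusted p = 4.97e-08, but adjusted p = 0.231 with an estimated correlation).

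The remaining calls of this comparison were lost with an estimated correlation. For ribosome biogenesis, NF-kB and basal genes that estimate was below the preset, so correlated members are not the reason. YAP/TEAD targets had 6 of 14 members higher and 0 lower (camera adjusted p = 0.0109, with an estimated correlation adjusted p = 0.192), and the call was lost without both cytoplasmic PELP1 replicate 1 and wild-type PELP1 replicate 2 (0.0616), in a range from 0.00172 to 0.192 over the alternatives. Endoplasmic reticulum chaperones had 5 of 19 higher and 1 lower (0.0145, with an estimated correlation adjusted p = 0.321). NRF2 genes had 3 of 18 higher and 0 lower (0.0347, with an estimated correlation adjusted p = 0.324), and the call was lost without wild-type PELP1 replicate 1 (adjusted p = 0.108) or cytoplasmic PELP1 replicate 3 (0.168) and with no filter (0.0862), in a range from 0.00319 to 0.324. Ribosome biogenesis genes had 5 of 36 higher and 0 lower (0.00809, with an estimated correlation adjusted p = 0.0583). The member with the smallest adjusted p, TSR1, was higher by 0.67 on the log2 scale (limma adjusted p = 4.48e-05). It lies in the chromosome 17 stretch that was lower with wild-type PELP1. Epithelial and luminal genes had 6 of 29 lower and 1 higher (0.00155, with an estimated correlation adjusted p = 0.178 and with quantile normalization 0.213, in a range from 0.000394 to 0.213). NF-kB genes had 3 of 18 lower and 0 higher (0.0109, with an estimated correlation adjusted p = 0.0837). Nuclear oxidative phosphorylation genes had 1 of 36 lower and 0 higher (0.0126, with an estimated correlation adjusted p = 0.615), and the call was lost without cytoplasmic PELP1 replicate 1 (adjusted p = 0.437) and with equal FPKM sums (0.061) or quantile normalization (0.294), in a range from 4.03e-06 to 0.641. Of 6 measured basal and myoepithelial markers, 3 were lower and 0 higher (0.0205, with an estimated correlation adjusted p = 0.121), and this call was lost without wild-type PELP1 replicate 2 (adjusted p = 0.395) or replicate 3 (0.0939), cytoplasmic PELP1 replicate 3 (0.0611) or vector replicate 3 (0.0699), with only the 6 libraries compared (0.109) and with no filter (0.476), in a range from 0.00147 to 0.476.

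Among the genes with the largest falls by the rule on level and overlap were the adhesion genes CEACAM5 and CEACAM6. They stood at 12 ± 1.21 against 45.6 ± 1.31 FPKM and at 45.1 ± 2.77 against 120.4 ± 5.32 FPKM. A separate entry, CEA, stood at 3.15 ± 1.91 against 12.1 ± 1.81 FPKM. These related entries may share reads, so the values of each may be only part of a signal. The hair keratin KRT81 stood at 543 ± 38.2 against 1385 ± 57.9 FPKM, again with close paralogs. TFF1 was lower by a log2 fold change of -1.45 (SE 0.11, limma adjusted p = 1.07e-05) and PGR by -0.99 (SE 0.13, limma adjusted p = 0.000705). EMC10 had the largest difference, -4.46 (SE 0.10, limma adjusted p = 1.69e-09). ESR1, NCOA3, CD44 and ALDH1A3 did not pass, with log2 differences of -0.21, 0.20, 0.15 and -0.10 (limma adjusted p-values of 0.325, 0.1, 0.473 and 0.743). ESR1 passed without cytoplasmic PELP1 replicate 1, with -0.42 (adjusted p = 0.00661, in a range to 0.657), and NCOA3 without cytoplasmic PELP1 replicate 3, with 0.26 (adjusted p = 0.0452, in a range to 0.290). Over all genes, 1211 were higher and 646 lower (limma), of which 72 and 51 differed at least 2-fold. The share of higher genes was 65.2% in the deposited units, 79.6% with equal FPKM sums and 51.6% with median-of-ratios scaling. Without wild-type PELP1 replicate 3 the counts were 731 and 361, and without cytoplasmic PELP1 replicate 2 they were 744 and 436.

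The 2 PELP1 constructs were compared through the vector libraries they share. With PELP1 itself left out, 486 genes were higher with both constructs and 376 lower with both, where independent lists of these sizes would share 107 and 88.8. The lists held 2010 and 648 genes that were higher and 1506 and 718 that were lower with cytoplasmic and wild-type PELP1. In 20 simulations of unchanged groups against the same controls, 0.1 and 0.05 genes were called higher on average and 0 were shared, which is too few calls to say anything about the overlap of lists of this size. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.61, against 0.50 in the simulations, and the covariance was 0.0588 against 0.00852. The simulations held the same shared controls, and their highest covariance was 0.0101. Library noise in the shared controls, as simulated, thus does not account for the excess in covariance of 0.0503 over the simulated mean. Anything particular to the vector libraries would still enter both comparisons, since 3 libraries cannot be split so that each part keeps 2. Among the genes that went the same way were CD74, at 23.0 ± 2.88 and 15.6 ± 1.99 FPKM with cytoplasmic and wild-type PELP1 against 6.26 ± 0.58 with vector, and CDKN1A, at 110 ± 1.66 and 159 ± 4.48 FPKM against 208 ± 1.88 (SD, n = 3).

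Other lists were not called in any comparison by camera with the preset correlation and the settings given above, and some were called under other settings or by fry, as stated below. For cytoplasmic PELP1 against vector, wild-type PELP1 against vector and cytoplasmic against wild-type PELP1 in turn, progestin and glucocorticoid induced genes had 0, 1 and 1 members higher and 2, 2 and 2 lower of 13. Cholesterol biosynthesis genes had 7, 2 and 4 higher and 2, 2 and 1 lower of 24. Immediate early and ERK feedback genes had 5, 4 and 3 higher and 7, 3 and 5 lower of 25. TGF-beta/SMAD targets had 5, 4 and 2 higher and 2, 2 and 1 lower of 17, with the receptor decoy BAMBI rising from 97.7 ± 1.27 FPKM with vector to 237 ± 11.8 FPKM with cytoplasmic PELP1. Wnt and Notch targets had 1, 0 and 1 higher and 2, 1 and 1 lower of 10. Mesenchymal genes had 1, 0 and 2 higher and 1, 1 and 0 lower of 8, and stem and progenitor markers 5, 4 and 2 higher and 3, 2 and 1 lower of 13. Squamous differentiation genes had 2, 2 and 1 higher and 0, 0 and 1 lower of 10. ERBB and insulin/IGF signalling genes had 5, 3 and 5 higher and 4, 2 and 3 lower of 21, and nuclear receptor coregulators 2, 0 and 1 higher and 1, 0 and 0 lower of 16. Squamous differentiation genes were called higher for wild-type PELP1 against vector without vector replicate 1 (adjusted p = 0.0196) or wild-type PELP1 replicate 2 or 3 (0.0399 and 0.0443) and with equal FPKM sums (0.0384), in a range from 0.00332 to 0.255. TGF-beta/SMAD targets were called higher for cytoplasmic PELP1 against vector without cytoplasmic PELP1 replicate 1 (adjusted p = 0.0283, in a range from 0.00126 to 0.404). Nuclear receptor coregulators were called higher for cytoplasmic against wild-type PELP1 without cytoplasmic PELP1 replicate 3 (adjusted p = 0.0405, in a range to 0.617). Lists called in another comparison gained calls as well. ATF4 response genes, with 10 higher and 4 lower of 25 for cytoplasmic PELP1 against vector (adjusted p = 0.0635), were called higher without vector replicate 3 (0.0328) or cytoplasmic PELP1 replicate 1 (0.0286), with no filter (0.0348) and with quantile normalization (0.0242), in a range from 0.00119 to 0.534. NF-kB genes, with 2 higher and 0 lower of 18 for wild-type PELP1 against vector (adjusted p = 0.0639), were called higher without vector replicate 2 (0.0496) or wild-type PELP1 replicate 2 (0.0399) and with equal FPKM sums (0.0405), in a range from 0.00646 to 0.237. Cytosolic ribosomal proteins, with 4 higher and 0 lower of 37 for cytoplasmic PELP1 against vector (adjusted p = 0.521), were called higher without cytoplasmic PELP1 replicate 1 (1.87e-06), with equal FPKM sums (0.014) and with quantile normalization (2.46e-05), in a range from 1.87e-06 to 0.866. For several uncalled lists the median, the mean and the camera direction differed in sign. Estrogen receptor targets had means of 0.06, 0.05 and 0.01 and medians of -0.03, -0.04 and 0.03 in the 3 comparisons, with a downward direction in each. ERBB and insulin/IGF genes had means of 0.06, 0.02 and 0.04 and medians of -0.06, -0.05 and 0, with directions down, up and down. Signs also differed for progestin and glucocorticoid and for Wnt and Notch genes in the first comparison, for immediate early genes in the first and the third, for p53 targets, YAP/TEAD targets and coregulators in the second, and for stem and progenitor markers in the third.

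Fry, which tests whether the genes of a list move 1 way on balance and does not compare them with other genes, called further lists. Each adjusted p is followed by the highest over the alternatives, and was the lowest of them unless stated. For cytoplasmic PELP1 against vector, fry called progestin and glucocorticoid genes (adjusted p = 0.0313, highest 0.47) and basal markers (0.0464, highest 0.83) lower. It called estrogen receptor targets (0.0327, highest 0.965), cholesterol biosynthesis (0.0117, highest 0.654), chaperones (0.0191, highest 0.654), squamous genes (0.0185, highest 0.81), the ATF4 response (0.00119, highest 0.534) and TGF-beta/SMAD targets (0.00126, highest 0.404) higher. For wild-type PELP1 against vector, it called Wnt and Notch targets lower (0.00646, highest 0.61) and NF-kB genes (0.00646, highest 0.237), squamous genes (0.00332, highest 0.255) and basal markers (0.0141, highest 0.671) higher. For cytoplasmic against wild-type PELP1, it called estrogen receptor targets (0.0216, highest 0.86), cholesterol biosynthesis (0.0318, highest 0.615), TGF-beta/SMAD targets (0.00327, highest 0.731), Wnt and Notch targets (0.0271, highest 0.782) and mesenchymal genes (0.0403, highest 0.796) higher. Coregulators were also called higher (0.0474, in a range from 0.0405 to 0.617). Squamous genes (0.0414, highest 0.284) and ERBB and insulin/IGF genes (0.0281, highest 0.622) were called lower, the latter with a mean of 0.04. Fry did not call 3 results that camera called, nuclear oxidative phosphorylation for cytoplasmic PELP1 against vector (adjusted p = 0.305, in a range from 6.04e-05 to 0.654) and against wild-type PELP1 (0.457, from 4.03e-06 to 0.641), and cytosolic ribosomal proteins for wild-type PELP1 against vector (0.437, from 4.83e-08 to 0.837).

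Adjusted over the list alone, the counts for cytoplasmic PELP1 against vector were 26 higher and 0 lower for hypoxia, 19 and 0 for glycolysis, 34 and 1 for the cell cycle, 28 and 1 for interferon-stimulated genes, 12 and 0 for antigen presentation, 4 and 13 for p53 targets and 0 and 13 for mitochondrial mRNAs. They were 7 and 1 for fatty acid synthesis, 10 and 1 for NRF2, 11 and 1 for ribosome biogenesis, 5 and 0 for YAP/TEAD, 2 and 10 for epithelial and luminal identity and 0 and 4 for nuclear oxidative phosphorylation. For wild-type PELP1 against vector they were 25 and 2 for the cell cycle, 21 and 3 for interferon-stimulated genes, 1 and 14 for the ATF4 response and 0 and 0 for cytosolic ribosomal proteins. For cytoplasmic against wild-type PELP1 they were 26 and 0 for hypoxia, 20 and 0 for glycolysis, 35 and 1 for the cell cycle, 22 and 0 for interferon-stimulated genes, 17 and 0 for the ATF4 response, 2 and 9 for p53 targets, 0 and 12 for mitochondrial mRNAs, 11 and 1 for fatty acid synthesis and 11 and 0 for antigen presentation. They were 7 and 0 for YAP/TEAD, 5 and 1 for chaperones, 6 and 0 for NRF2, 5 and 0 for ribosome biogenesis, 3 and 9 for epithelial and luminal identity, 1 and 7 for NF-kB, 0 and 0 for nuclear oxidative phosphorylation and 0 and 3 for basal markers.

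Markers of other cell types and signs of RNA selection were read as well. Of 11 fibroblast markers in the file, 1 passed the filter, COL1A1, with 2.85 ± 0.72, 3.64 ± 1.24 and 2.94 ± 0.38 FPKM with vector, wild-type PELP1 and cytoplasmic PELP1 (SD, n = 3). Of 21 immune and endothelial markers 4 passed, and the highest, CD68, had 2.00 ± 0.55, 1.71 ± 0.38 and 2.23 ± 0.62 FPKM. Both lists, and the metallothioneins, with 4 of 9 genes passing and MT2A at 32.2 ± 3.05, 27.6 ± 3.65 and 39.4 ± 5.1 FPKM, had too few measured members for a list test. Of 7 measured replication-dependent histone genes, whose mRNAs lack a poly(A) tail, 1, 0 and 1 were higher and 1, 1 and 0 lower in the 3 comparisons, and camera did not call the list (adjusted p = 0.827, 0.660 and 0.517). Fry called it higher for cytoplasmic against wild-type PELP1 (adjusted p = 0.0104, in a range from 0.0104 to 0.895).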

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

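The tests of the difference between the 2 constructs were planned as a comparison, whereas their reading as opposite effects, and every test of an explanation here except the splits of the libraries, was chosen after the results were seen. Called genes went in opposite directions against vector for 59 genes, where independent lists of these sizes would give 199. That number leaves out the shared vector libraries, which alone gave fold changes correlated by 0.50 in the simulations, so the gap between 59 and 199 is not read as an effect. All 59 had a called difference between the constructs themselves, which nearly follows from called changes in opposite directions against the same libraries. Of the 59, 6 lie between PELP1 and the end of the short arm of chromosome 17, where most genes were lower with wild-type PELP1. NDRG1 had log2 fold changes of 1.25 with cytoplasmic and -0.85 with wild-type PELP1, and the hypoxia-induced gene ANKRD37 had 0.81 and -0.96. PSMB8 had 0.38 and -1.50, PHGDH 0.44 and -0.49, and the phosphatase gene DUSP4 0.25 and -0.81. CEACAM5 had -0.95 and 0.94, CEACAM6 -0.55 and 0.85, and KRT81 -0.25 and 1.10.

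The difference of cytoplasmic minus wild-type PELP1 was tested for each list with camera, which compares its members with all other genes. With an estimated correlation 4 lists were still called. Their mean log2 differences, which camera does not test, were 0.91 for hypoxia targets, 0.42 for the cell cycle, 0.24 for interferon-stimulated genes and -0.16 for p53 targets.

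The 48 hypoxia and glycolysis genes, pooled, were higher in the cytoplasmic PELP1 libraries than with vector by a median of 0.66 (95% interval 0.45 to 0.79). A trend with GC content, transcript length and expression is argued against, since removing it left a median of 0.69 (0.39 to 0.88, for the 47 genes with a value). Gains of chromosome segments are argued against as the whole cause, since subtracting the median of the 20 neighbouring genes left 0.58 (0.43 to 0.75). A difference in tumorsphere culture or library batch between the lines cannot be told apart from the construct, because the shallowest cytoplasmic PELP1 library had 1.41 times the depth of the deepest other library and no other group shares that depth. Other differences between the lines cannot be told apart from the construct either, and an effect of cytoplasmic PELP1 also stays open.

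The 13 mitochondrial mRNAs were lower with cytoplasmic PELP1 than with vector, by a median of -1.49. Scaling is argued against by the median of -1.52 with median-of-ratios scaling, and a trend with GC content, length and expression by the median of -1.53 once it was removed (-1.71 to -1.27). That interval covers only the spread between the 13 mRNAs, whose values move together, and not the spread between libraries. The library with the lowest values is not the whole cause, since without cytoplasmic PELP1 replicate 1 the median was -1.07 and 11 of the 13 mRNAs were still called lower. RNA preparation that differed between libraries remains a possible explanation, as the largest range within a group was 0.91 of the largest difference between group means (1.29 against 1.41 on the log2 scale). A lower mitochondrial mRNA content with cytoplasmic PELP1 also stays open.

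For each comparison the 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. In fits of the 6 libraries, the real split gave 3258 genes for cytoplasmic PELP1 against vector, 1599 for wild-type PELP1 against vector and 1447 for cytoplasmic against wild-type PELP1. In each case 1 of the 10 splits, the real one, gave as many, and the highest other split gave 1 gene. Every other split mixes libraries of both groups, so a difference between the groups, of any cause, enters the spread and lowers the calls. The other splits therefore do not show what unchanged groups would give.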

How the results depend on the processing

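Pseudocounts, quantile normalization, no variance trend, leaving out both cytoplasmic PELP1 replicate 1 and wild-type PELP1 replicate 2 and leaving out the chromosome 17 genes were added after seeing the data. Each alternative changed 1 choice. The PELP1 log2 fold changes against vector kept their direction and stayed past the threshold under all of them. The planned count test, an edgeR quasi-likelihood fit, was not run, since it needs counts. Of 7107 values for named genes under the alternatives, 6740 kept their direction and side of the threshold, 316 fell short of it, 51 came to pass it and 0 reversed. Of 2067 values for lists, 1955 kept both, 59 fell short, 49 came to pass and 4 reversed. With fry, estrogen receptor targets were called higher by a mean of 0.059 (cytoplasmic against vector) and 0.013 (cytoplasmic against wild-type), where camera gave an uncalled fall. Cytosolic ribosomal proteins, uncalled and lower for cytoplasmic against wild-type PELP1, were called higher by a mean of 0.116 with quantile normalization and 0.081 without both cytoplasmic PELP1 replicate 1 and wild-type PELP1 replicate 2. They were called lower by means of -0.081 with median-of-ratios scaling and -0.068, -0.065 and -0.127 without wild-type PELP1 replicate 1 or cytoplasmic PELP1 replicate 2 or 3, so no direction is given for this list.

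For cytoplasmic PELP1 against vector, leaving out single libraries gave 1453 to 1982 genes higher, 1051 to 1576 lower and 12 to 14 lists called. For wild-type PELP1 against vector it gave 391 to 822 higher, 419 to 917 lower and 4 to 6 lists, and for cytoplasmic against wild-type PELP1 731 to 1112 higher, 361 to 716 lower and 16 to 18 lists. Equal FPKM sums gave 401 genes lower for cytoplasmic against wild-type PELP1 and 7 lists for wild-type PELP1 against vector. Camera with an estimated correlation called 3, 2 and 4 lists in the 3 comparisons, in the order above, and fry called 20, 7 and 25. Requiring 2-fold changes left 23 genes higher and 20 lower with both constructs. Without both cytoplasmic PELP1 replicate 1 and wild-type PELP1 replicate 2, 1750 genes were higher and 1223 lower for cytoplasmic PELP1 against vector. The cause was not tested, except that requiring 2-fold changes lowers a count by construction.

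The replicate numbers do not pair the libraries. Deviations of same-numbered libraries correlated between -0.07 and 0.06, and 1 of 9 libraries correlated best with its own number. With the replicate block, 1966 genes were higher and 1505 lower for cytoplasmic PELP1 against vector, 590 and 659 for wild-type PELP1 against vector and 1128 and 646 for cytoplasmic against wild-type PELP1, where the block also called cytosolic ribosomal proteins lower (-0.043). With the block, CD44 also lost its call for cytoplasmic PELP1 against vector (limma adjusted p = 0.0519). Genes near the FPKM filter rest on few fragments in the vector and wild-type PELP1 libraries, which were shallower than every cytoplasmic PELP1 library.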

Other observations

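The tests in this part were all chosen after the results they concern were seen. EMC10 was nearly absent from all 3 cytoplasmic PELP1 libraries, at 0.54, 0.43 and 0.67 FPKM, and was at 18.4, 18.6 and 18.1 FPKM with vector and at 21.3, 24.9 and 21.5 FPKM with wild-type PELP1. The hair keratins KRT81, KRT83, KRT85 and KRT86, close paralogs in 1 gene cluster whose reads cannot be assigned with certainty, all rose with wild-type PELP1 against vector, with log2 fold changes of 1.10, 1.00, 0.98 and 0.84 (limma adjusted p = 3.43e-06, 3.16e-05, 0.000482 and 2.95e-05). With cytoplasmic PELP1 against vector they had -0.25, -0.02, -0.18 and -0.20, of which KRT81 and KRT86 passed (limma adjusted p = 0.0186, 0.876, 0.285 and 0.0443). The direct differences of cytoplasmic minus wild-type PELP1 were -1.35, -1.02, -1.16 and -1.04, and all 4 passed (limma adjusted p = 7.18e-07, 1.93e-05, 0.000126 and 4.26e-06).

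Neighbouring genes changed together. The Spearman correlation across genes between the log2 fold change of a gene and that of the next tested gene on the chromosome was 0.22 for cytoplasmic PELP1 against vector, 0.19 for wild-type PELP1 against vector and 0.16 for cytoplasmic against wild-type PELP1, over 12004 pairs. Genes are not independent replicates. In 1000 shuffles of the genes it did not exceed 0.04, 0.03 and 0.03 (permutation p = 0.001 each, the smallest these shuffles can give, and 0.001 after adjustment over the 3). On chromosome 4 the 57 genes from QDPR to OCIAD2 had a median log2 fold change of 0.40 with cytoplasmic and 0.33 with wild-type PELP1 against vector. With cytoplasmic PELP1 against vector, 57 genes on chromosome 1 from ZBTB37 to KIF14 had a median of 0.38, and 57 genes on chromosome 5 from FAM151B to EPB41L4A one of 0.34.

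The 57 genes telomeric of PELP1 on the short arm of chromosome 17 were lower with wild-type PELP1 than with vector by a median of -0.43, a ratio of 0.74, and their medians were -0.42, -0.39 and -0.43 in the 3 wild-type PELP1 libraries. A trend with GC content, length and expression is argued against by the median of -0.40 after its removal (-0.46 to -0.32, for 54 of the 57 genes). No other window of 57 neighbouring genes had a median as low (0 of 10682, the lowest being -0.19). This cannot exclude chance clustering along chromosomes, since the stretch was chosen because its genes were low. In the other direction, the 57 genes on chromosome 4 reached 0.33 in the same comparison. A candidate explanation is that the wild-type PELP1 line lost 1 copy of the chromosome end from the CRISPR target outward. The test of where the step lies did not settle this: the break with the largest difference of medians, 0.43, was displaced from PELP1 by -8 genes (negative is telomeric), after ZZEF1, and the genes in between were called lower (MYBBP1A and ALOX15 at -0.37 and -0.44) except SPNS2 and SMTNL2, which had 0.15 and 0.30 and did not pass. A second estimate of the break, after UBE2G1, was displaced from PELP1 by -5 genes. The medians on the telomeric and centromeric sides of PELP1 itself, -0.43 and -0.01, differ by nearly as much as the largest difference, so the step cannot be placed exactly. The knockout came before the constructs, and a loss shared by all knockout cells would not set the wild-type PELP1 line apart. The telomeric medians of the cytoplasmic PELP1 libraries were -0.03, -0.03 and 0.01. A loss would thus have to be particular to the wild-type PELP1 line, and how it could have arisen was not tested. Gene dosage was not measured, and regulation of these genes by wild-type PELP1 stays open and untested.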
